A study of Homo sapiens with 6 samples.

How the data were processed

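Total RNA of P493 cells was extracted with Trizol and cleaned up on columns with DNase treatment, and biotinylated cRNA was made with a MessageAmp kit for Illumina arrays, per the labels' protocols. The groups were taken from the sample titles, with 3 arrays of shControl cells and 3 of shTERT cells. The main table holds, per the file headers, non-normalized probe intensities and a detection p-value for each of 47323 probes on each of 6 arrays. The intensity values were deposited on a linear scale without background subtraction, with lowest values of 25.5 to 31.4. The detection p-value was deposited for each probe and array, and how it was computed, the scanner software and the array version are not given in the sources used here. A second deposited table holds the authors' own processed intensities of the same arrays. Its columns share 1 distribution (medians 61.4 to 61.5, highest value 19973), are linear, and rank the probes of each array exactly as the scanner values do. The mean of the highest scanner values was 19578, so the target distribution is not the plain mean of these 6 arrays, and how it was made is not given in the sources used here. That table was used only as an alternative.

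Signals were background-corrected by normexp with the background estimated from the detection p-values, offset by 16, quantile-normalized between arrays and taken to log2 (neqc, limma 3.58.1, R 4.3.3). A probe was kept if its detection p-value was under 0.05 on at least 3 of the 6 arrays, whatever their group, which left 17393 probes. Gene names came from the platform annotation, with symbols updated through gene numbers to the RefSeq annotation of GRCh38.p14. In that annotation 30113 probes had 1 gene, 8 several and 17202 none, and for 30074 probes the gene number was found in the reference. Of the kept probes 13493 had 1 gene, 3 several and 3897 none, and no gene was named from a probe with several. A gene was represented by its kept probe with the highest mean over all arrays, giving 10305 genes. Of these, 2586 had more than 1 kept probe, and 42 had probes called in both directions. The genes named by the rule below had 47 other kept probes, of which 4 differed in the opposite direction, none past the threshold, and these are given where the gene is named. The 18 genes named after their values were seen had 4 other kept probes, 0 in the opposite direction.

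Groups were compared with limma (lmFit and eBayes), with Benjamini-Hochberg adjustment over all kept probes and a threshold of adjusted p under 0.05. All adjusted p-values of genes are from limma. The TERT probes were fitted without the detection filter. A gene undetected on every array of 1 group (248 genes in shControl, 52 in shTERT) has only a bound there. Its difference is given as at least N-fold, the mean of the detected group against the mean over the other group's arrays of the higher of the lowest detected value and the probe's own value, and no fold is given where that came to under 1. The same bound is given for a named gene detected on some arrays of the dimmer group whose mean there lay below the mean of the lowest detected values (SPRR2C, UMODL1, HEY2, CDH1, TYROBP and ZAP70). Gene lists were tested with camera from limma (correlation preset at 0.01) on 1 probe per gene, adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it.

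The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule names TERT and MYC, then the 12 genes with the largest fold in each direction among called genes with no overlap between groups and a proper gene symbol, then up to 4 members with the smallest p-value from each list. The lists, from textbook knowledge and not from these samples, were MYC-induced genes, MYC-repressed genes, ribosome biogenesis, cytosolic ribosomal proteins, nucleotide synthesis, glycolysis, oxidative phosphorylation, DNA replication and G1/S, mitosis and G2/M, p53 targets, interferon-stimulated genes, NF-kB targets, unfolded protein response, ATF4 and amino acid response, cholesterol synthesis, Wnt and beta-catenin targets, MHC class II and antigen presentation, B-cell identity, plasma cell markers, T and NK cell markers, myeloid cell markers, stromal and epithelial markers, telomerase and shelterin, MYC partners and MYC stability, and immediate early genes. Some genes stand in more than 1 list.

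Alternatives were no filter and a stricter filter (detection p under 0.01 on all 6 arrays), no background correction, normexp with offset 50, median scaling, cyclic loess, the authors' values, the replicate number as a block, an intensity trend with robust estimation, array weights, an ordinary test per probe, the mean of a gene's probes and leaving out each array. A block for the chip could not be fitted, as no chip is named in the sources used here.

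The procedure was tested on simulated data made from the real arrays, with 200 probes changed. Of 50 probes changed 4-fold 80% were called, of 50 changed 2-fold 64%, of 50 changed 1.5-fold 36% and of 50 changed 1.25-fold 0%, over 16397 probes tested, and every call had the right direction. Of 16182 unchanged probes 9 were called (0.0556%), a list shifted by 0.5 passed, and 0 of 23 lists without shifted genes passed. Noise was drawn separately for each probe, so members of a list were uncorrelated. On the real arrays the correlation was estimated at 0.174 for the interferon-stimulated genes and 0.165 for the mitosis genes. The simulation therefore does not show how often camera calls lists with correlated members. It also changed far fewer probes than the 7065 called on the real arrays. A first version of the simulation, which added noise on top of the measured noise, recovered fewer of the 4-fold changes and was replaced, and the share of 4-fold changes that the test had to recover was lowered at the same time. Figures were drawn with matplotlib 3.10.9.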

Results

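Transcript levels were measured on Illumina BeadChip arrays in P493 cells, a human B-cell line derived from Epstein-Barr virus-immortalised B cells and carrying a tetracycline-repressible MYC gene. Whether that gene was on or repressed in these cultures is not given in the sources used here, which bears on every difference in MYC and its targets below. The cells had been stably transduced with pLKO, a lentiviral vector that expresses a short hairpin RNA. One group carried a control hairpin (shControl, 3 arrays) and the other a hairpin against TERT, the catalytic subunit of telomerase (shTERT, 3 arrays). Each array reported 47323 probes. Of these, 34.74% to 37.35% on the shControl arrays and 37.82% to 39.0% on the shTERT arrays were detected above the array's background at a detection p-value under 0.05. Every shTERT array thus had more detected probes than every shControl array, which bears on genes undetected in 1 group. The median signal lay between 53.7 and 69.8. The 3 shControl arrays correlated with each other at 0.986 to 0.992 over log2 values and the 3 shTERT arrays at 0.993 to 0.994, while the highest correlation between the groups was 0.965. The number of arrays limits the precision of every value below. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

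The series addresses the relation of TERT to MYC, and its arrays allow 1 comparison, shTERT against shControl. Interferon-stimulated genes, the antiviral genes that interferon signalling switches on, were lower in shTERT cells: 29 of the 30 measured members fell, with a median difference of 2.47-fold (log2 -1.30, quartiles -1.95 and -0.86, n = 3 arrays per group). Genes of mitosis and G2/M were higher, with 31 of 33 measured members up and a median difference of 2.13-fold (log2 1.09, lower quartile 0.76). Genes of DNA replication and genes that MYC induces also rose as groups, by medians of 1.27-fold and 1.24-fold; these 4 lists passed limma camera at adjusted p from 5.33e-18 to 0.00698, and none of them with an estimated correlation (adjusted p 0.192 to 0.317). The transcript of MYC itself, the growth-promoting transcription factor, was 1.46-fold higher in shTERT cells by the brighter of its probes (log2 difference 0.55, SE 0.11, n = 3 per group, limma adjusted p = 0.00746). TERT could not be measured on these arrays.

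Both TERT probes, ILMN_2373119 and ILMN_1796005, lay below the detection threshold on all 6 arrays. Their normalized log2 means were 4.49 ± 0.06 (SD, n = 3) in shControl and 4.48 ± 0.10 in shTERT for the first, and 4.42 ± 0.04 and 4.44 ± 0.04 for the second. The group differences, -0.01 (SE 0.08) and 0.02 (SE 0.06), compare background with background, and no fold is given. The targeted gene therefore does not check the group labels, and every direction below rests on the labels as given.

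MYC was detected on all 6 arrays by both of its probes. For ILMN_1680618 the log2 mean was 10.13 ± 0.15 (SD, n = 3) in shControl and 10.68 ± 0.12 in shTERT, with no overlap between the groups. The second MYC probe, ILMN_2110908, differed by 0.20 (SE 0.08) in the same direction and did not pass the threshold (9.28 ± 0.03 against 9.48 ± 0.08, limma adjusted p = 0.104).

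**Figure D1:**
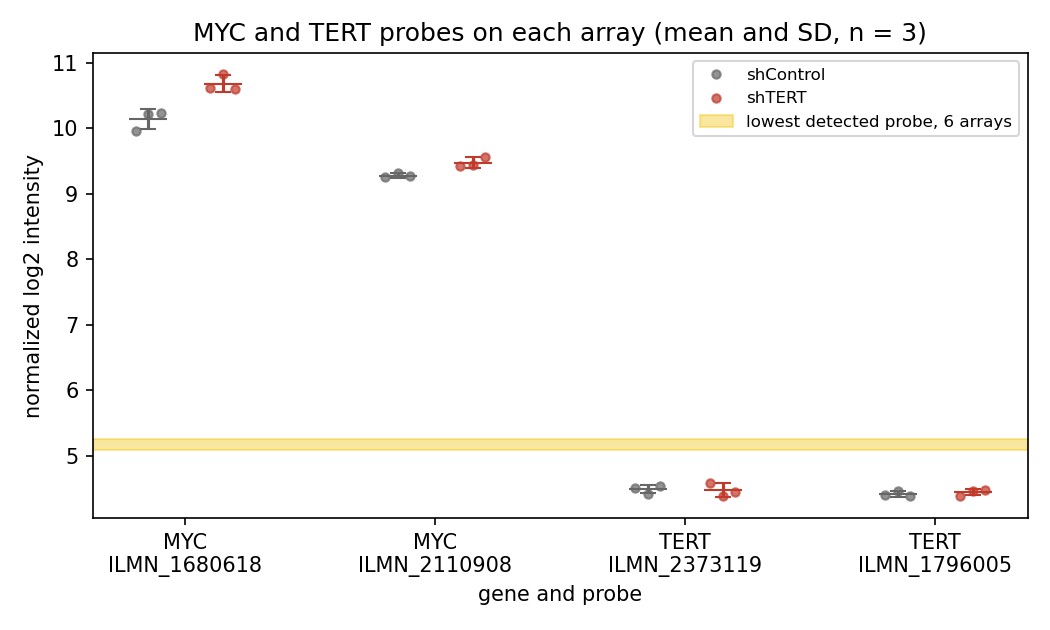
Normalized log2 intensity (vertical axis) of the MYC and TERT probes (horizontal axis) on each array, with points for single arrays, a dash for the mean of 3 arrays and bars for the SD; the yellow band spans the lowest detected value on each of the 6 arrays. The MYC probes lie well above the band, with shTERT above shControl by 0.55 and 0.20, and the TERT probes lie below it in both groups.

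Of 10305 genes tested, 4584 (44.5%) changed at a limma adjusted p under 0.05, 2469 of them higher and 2115 lower in shTERT. A change of at least 1.5-fold was seen in 2325 genes (1292 higher, 1033 lower), and of at least 2-fold in 401 higher and 309 lower genes. The count at 1.5-fold fell to 1335 without background correction and to 1339 with a larger offset, both of which leave more background in the values. In 5954 genes (57.8%) the values of the groups did not overlap, where chance gives 10%.

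The largest rises were led by genes not detected in shControl. STMN3, a stathmin-family regulator of microtubules, was at least 16.9-fold higher in shTERT (log2 mean 9.27 ± 0.08 against 4.92 ± 0.24, SD, n = 3). MAGEA2, a cancer-testis antigen with near-identical gene copies that the probe may also read, was at least 12.6-fold higher, and MMP7, a matrix-degrading metalloproteinase, at least 5.75-fold higher. Among genes detected in both groups, RTL3, a retrotransposon-derived gene, rose 8.83-fold (log2 3.14, SE 0.15). HEY1, a transcriptional repressor induced by Notch, rose 6.70-fold and was detected on 2 of the 3 shControl arrays. PHACTR1, a regulator of actin and protein phosphatase 1, rose 6.56-fold, and CCL4L1, a chemokine gene with near-identical paralogs, 5.62-fold. The small nucleolar RNA gene SNORA12 rose 5.54-fold, CCDC92 4.96-fold, the actin-bundling protein gene PLS3 4.89-fold, the lymphocyte receptor gene CD6 4.84-fold and CYP4F3, which encodes a leukotriene B4 hydroxylase, 4.70-fold. A second PLS3 probe also passed, with a log2 difference of 1.37 against 2.29 by the brightest. These folds and bounds hold for the background correction used, and without it the log2 differences came to 3.05 for STMN3, 2.54 for MAGEA2, 1.85 for MMP7 and HEY1, 1.63 for CYP4F3 and 1.56 for CCDC92.

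The largest fall was in IFI27, an interferon-induced gene, which was 15.5-fold lower in shTERT (log2 mean 8.08 ± 0.09 against 12.03 ± 0.09, SD, n = 3, limma adjusted p = 3.5e-06). SPRR2C was at least 8.93-fold lower, detected on 1 of the 3 shTERT arrays with a mean below the lowest detected values there. TNFSF10, the death ligand TRAIL, fell 7.85-fold, USP18, a protease that removes the interferon-induced modifier ISG15, 7.25-fold, and ENTHD1 6.27-fold. CD38, an NAD-consuming surface enzyme of activated B cells and plasma cells, fell 6.23-fold and was detected on 2 of the 3 shTERT arrays. SLC17A7, a vesicular glutamate transporter gene, was at least 5.01-fold lower and HESX1, a homeobox gene, at least 4.75-fold lower, both undetected on every shTERT array. IL23A, a subunit of interleukin 23, fell 5.63-fold, TMEM135 5.15-fold and IZUMO4 5.08-fold, and UMODL1, with a mean below the lowest detected values and detection on 1 of the 3 shTERT arrays, at least 4.73-fold. A second IZUMO4 probe also passed, with a log2 difference of -1.23 against -2.34 by the brightest. The limma adjusted p of these 24 genes with the largest rises and falls ranged from 3.5e-06 to 0.000155. Without background correction the log2 differences shrank to -2.23 for USP18, -2.09 for SPRR2C, -1.81 for ENTHD1, -1.74 for CD38, -1.71 for IZUMO4, -1.60 for TMEM135, -1.56 for SLC17A7, -1.54 for HESX1 and -1.42 for UMODL1, and with the larger offset TNFSF10 came to -2.01.

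**Figure D2:**
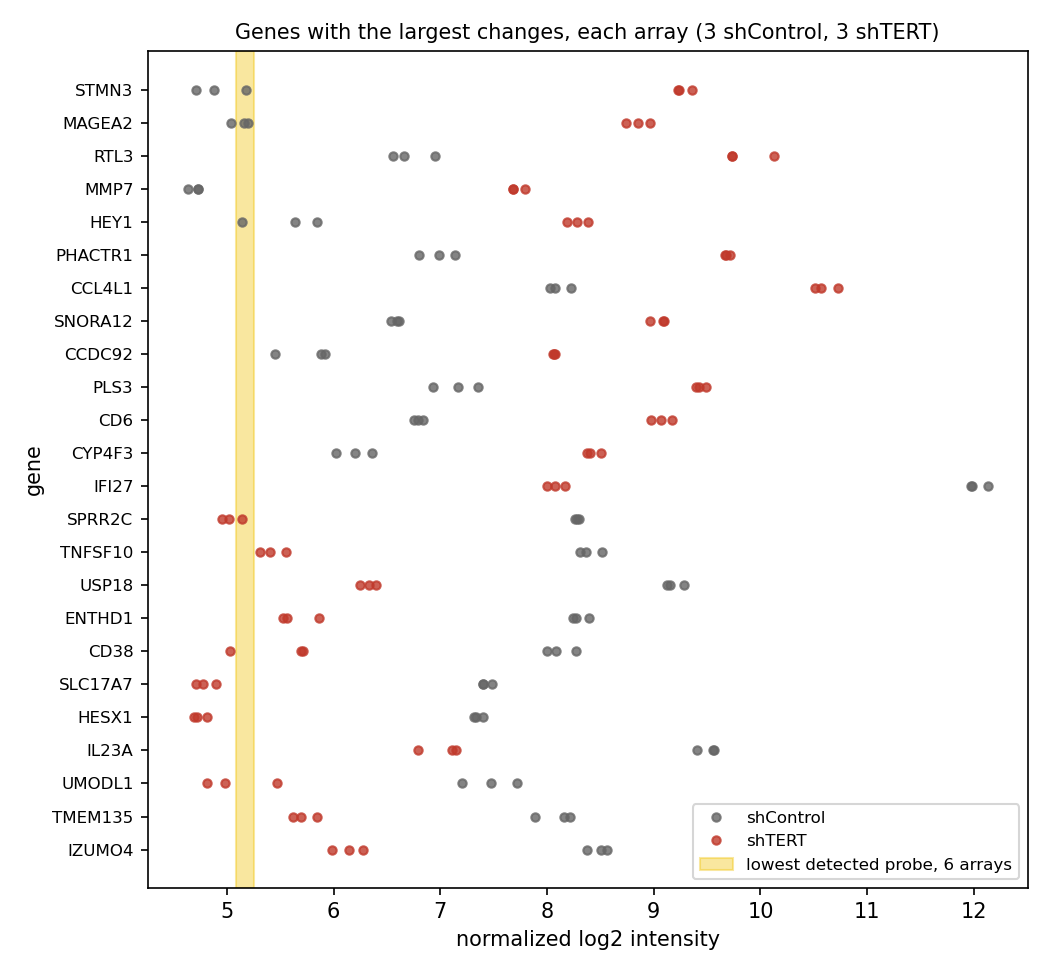
Normalized log2 intensity (horizontal axis) of the 24 genes with the largest rises and falls (vertical axis), 1 point per array, 3 shControl and 3 shTERT; the yellow band spans the lowest detected value on each of the 6 arrays. IFI27 moved from about 12.03 to 8.08, and STMN3, MAGEA2 and MMP7 rose from the background band or below it.

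Among the interferon-stimulated genes, IFI27 and USP18 were followed by ISG20, an exonuclease, which fell 4.70-fold (log2 -2.23, SE 0.09), and OASL, a relative of the oligoadenylate synthetases, which fell 4.09-fold (log2 -2.03, SE 0.08). No member rose, MX2 did not pass the threshold, and the counts were the same adjusted over the list alone. The list stood apart from the other genes at an adjusted p of 5.33e-18 (limma camera with a preset correlation), which became an adjusted p of 0.192 with an estimated correlation. Among the mitosis genes, CDC20, an activator of the anaphase-promoting complex, rose 4.65-fold (log2 2.22, SE 0.12), the cyclin gene CCNB2 3.53-fold, the topoisomerase gene TOP2A 3.46-fold and the centromeric histone gene CENPA 3.20-fold. ECT2, a regulator of cytokinesis singled out here after its values were seen, was the 1 member that fell, a call lost under median scaling (limma adjusted p = 0.237) and without any 1 of 3 of the arrays (limma adjusted p 0.0531 to 0.0629), and 32 members rose adjusted over the list alone. The adjusted p was 8.53e-13 by camera and 0.192 with an estimated correlation.

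DNA replication and G1/S genes rose in 21 of 38 measured members and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.317 with an estimated correlation). GINS2, a subunit of the replicative helicase, rose 2.64-fold, CDT1, a licensing factor, 2.33-fold, the sliding clamp gene PCNA 1.87-fold and the helicase gene MCM7 1.68-fold. A second PCNA probe gave 0.57 on the log2 scale at an adjusted p of 0.0579. Of 25 measured genes of nucleotide synthesis 9 rose and 2 fell (11 and 2 adjusted over the list alone), among them the purine synthesis genes ADSL (1.85-fold), IMPDH1 (2.05-fold) and PFAS (1.51-fold) and the kinase gene NME1 (1.43-fold), all higher. The list missed the threshold (camera adjusted p = 0.0599, or 0.357 with an estimated correlation) and passed without the detection filter (adjusted p = 0.00695). Neither of the other IMPDH1 probes passed the gene threshold (log2 0.45 for IMPDH1 as the mean of its probes), while of the other NME1 probes 1 passed (log2 0.44, limma adjusted p = 0.0141) and 1 did not (0.22, limma adjusted p = 0.126).

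MYC-induced genes rose in 21 of 47 measured members and fell in 4 (22 and 4 adjusted over the list alone), with a median log2 difference of 0.31, or 0.29 with the dim members at their bounds (camera adjusted p = 0.00698; adjusted p = 0.192 with an estimated correlation). The nuclear importer gene IPO4 rose 2.09-fold, and the ribosome assembly genes MRTO4 and NIP7 rose 1.62-fold and 1.55-fold. ODC1, the rate-limiting enzyme of polyamine synthesis and a classical MYC target, went the other way and fell by 0.85 on the log2 scale (SE 0.09). The MYC-repressed genes split, with 8 of 22 higher and 4 lower by either adjustment, and their median (-0.04) and mean (0.17) differed in sign (camera, upward, adjusted p = 0.611). TXNIP, an inhibitor of thioredoxin, rose 3.07-fold, KLF2 3.06-fold (log2 0.92 without background correction) with detection on 2 of the 3 shControl arrays, and the PI3-kinase inhibitor gene PIK3IP1 2.07-fold, while the complement receptor gene CR2 fell 2.21-fold. Among MYC's partners and regulators of its stability, 7 of 17 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.395). SKP2, a ubiquitin ligase subunit, rose 2.13-fold, the MAX-binding repressor gene MXD4 1.89-fold and the mitotic kinase gene AURKA 1.56-fold. A second SKP2 probe also passed, with a log2 difference of 0.52 against 1.09 by the brightest. MAX, the dimerisation partner of MYC, was 1.75-fold lower by its brightest probe, but its other probes gave 0.31 and -0.14 on the log2 scale and did not pass, nor did the mean of its probes (-0.21).

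Cytosolic ribosomal protein genes rose in 12 of 48 and fell in 2 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0599), led by RPL29 (3.03-fold higher), RPS23 (2.21-fold), RPL34 (1.73-fold) and RPS7 (1.65-fold), all with processed pseudogenes that their probes may also read. The list passed with camera in 9 other settings, at adjusted p from 0.00617 to 0.0483, and missed in all other camera settings with that preset correlation (adjusted p 0.0533 to 0.0919) and with an estimated correlation (adjusted p = 0.192). Ribosome biogenesis genes went both ways, with 9 of 40 higher and 7 lower (10 and 7 adjusted over the list alone; camera adjusted p = 0.45), and the members with the smallest p-values, NOC3L (2.05-fold), DDX10 (1.91-fold), TAF1D (1.74-fold) and NMD3 (1.59-fold), were lower. In the telomerase and shelterin list, 2 of 20 rose and 5 fell by either adjustment (camera adjusted p = 0.53). The telomere-binding protein gene TERF2 fell 1.74-fold, its partner TERF2IP 1.53-fold and the telomere replication gene STN1 1.68-fold. TERF1 rose 1.70-fold by its brightest probe, with -0.06 and no call from another probe, and a second STN1 probe also made no call.

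Of 18 Wnt and beta-catenin targets with a probe only 8 passed the detection filter, and of these 6 rose and 1 fell, by either adjustment (camera adjusted p = 0.0306; adjusted p = 0.357 with an estimated correlation). Their median log2 difference was 0.90, against 0.16 over the list without the filter (camera adjusted p = 0.00641). AXIN2, a feedback inhibitor of Wnt signalling, rose 2.41-fold, TNFRSF19 2.38-fold (log2 0.66 without background correction) with detection on 1 of the 3 shControl arrays, the cyclin gene CCND1 2.26-fold and the transcription factor gene LEF1 1.84-fold. NF-kB targets fell in 15 of 28 and rose in 6, by either adjustment (camera adjusted p = 0.0384; adjusted p = 0.192 with an estimated correlation). The neutrophil chemokine gene CXCL8 fell 3.95-fold, the chemokine gene CCL22 3.78-fold and the NF-kB subunit gene NFKB2 3.22-fold, whereas CCL3, a macrophage inflammatory chemokine with close paralogs, rose 4.02-fold. Immediate early genes fell in 9 of 18 and rose in 3 (9 and 4 adjusted over the list alone; camera adjusted p = 0.0456; adjusted p = 0.357 with an estimated correlation). The anti-apoptotic gene MCL1 fell by 1.32 on the log2 scale, the phosphatase gene DUSP1 2.31-fold and the AP-1 subunit gene JUN 2.06-fold. A second MCL1 probe also passed, with a log2 difference of -0.47.

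**Figure D3:**
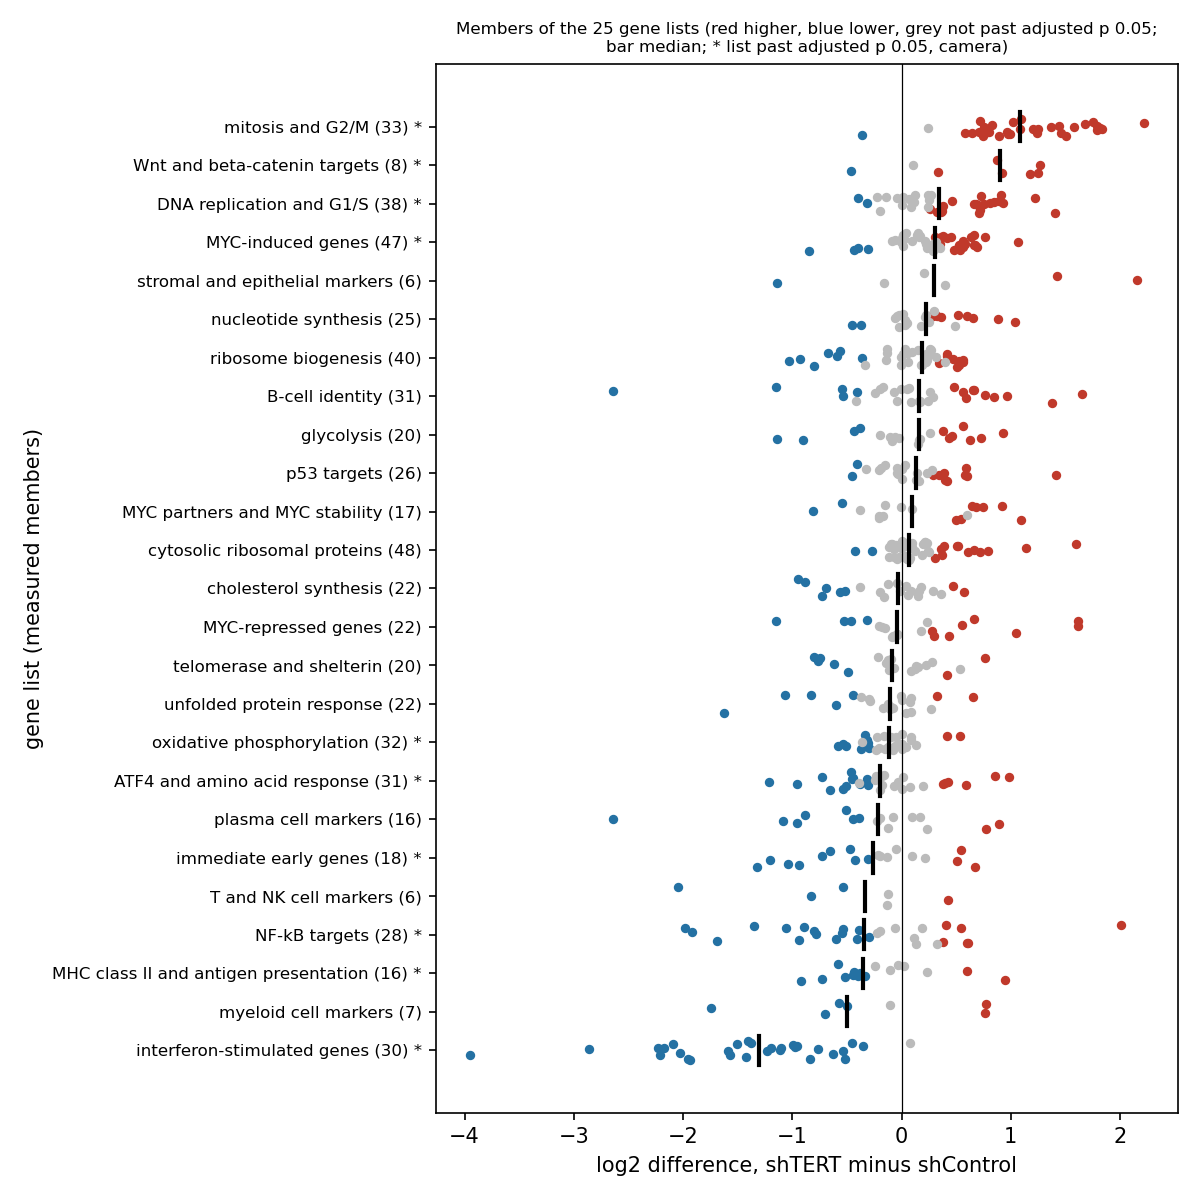
Log2 difference, shTERT minus shControl (horizontal axis), of each measured member of the 25 gene lists (vertical axis, number measured in brackets), 3 arrays per group; red and blue points passed an adjusted p of 0.05, black bars mark list medians and asterisks the 10 lists past the camera threshold. The interferon-stimulated genes lie almost wholly to the left (median -1.30) and the mitosis genes to the right (median 1.09).

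Genes of the ATF4 and amino acid response fell in 12 of 31 and rose in 6 (14 and 6 adjusted over the list alone; camera adjusted p = 0.0456; adjusted p = 0.192 with an estimated correlation). The tRNA synthetase gene NARS1 fell 2.31-fold, the serine synthesis gene PSAT1 1.95-fold and the stress-induced factor gene ATF3 1.66-fold, while the pseudokinase gene TRIB3 rose 1.98-fold. Oxidative phosphorylation genes fell in 9 of 32 and rose in 2, by either adjustment, with a median of -0.11 (camera adjusted p = 0.0456; adjusted p = 0.192 with an estimated correlation). The complex II gene SDHD fell 1.49-fold, the ATP synthase gene ATP5F1C 1.45-fold and the complex I gene NDUFA9 1.42-fold, and the complex IV gene COX4I1 rose 1.45-fold. MHC class II and antigen presentation genes fell in 9 of 16 and rose in 2 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0456; adjusted p = 0.192 with an estimated correlation). HLA-DOB fell 1.90-fold, the costimulatory ligand gene CD80 1.66-fold and the cathepsin gene CTSH by 0.58 on the log2 scale, with no call under median scaling (limma adjusted p = 0.0519), and HLA-DMA, a peptide-loading chaperone, rose 1.93-fold.

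The unfolded protein response list missed the threshold, with 5 of 22 lower and 2 higher by either adjustment (camera adjusted p = 0.11). The chaperone gene DNAJB11 fell 3.09-fold and SEC24D, of the secretory coat, 1.78-fold, and the ubiquitin ligase gene SYVN1 rose 1.57-fold. SELENOS fell 2.09-fold, with no call from a second probe and a call in the same direction from another. Cholesterol synthesis genes fell in 6 of 22 and rose in 2, by either adjustment (camera adjusted p = 0.262). DHCR7 fell 1.93-fold, MSMO1 1.84-fold, LSS 1.65-fold and SQLE 1.61-fold, all enzymes of the pathway, and of the other MSMO1 probes 1 made no call and 1 fell. Glycolysis genes rose in 7 of 20 and fell in 4 (8 and 4 adjusted over the list alone; camera adjusted p = 0.553). The glucose transporter genes SLC2A3 and SLC2A1 rose 1.90-fold and 1.65-fold, while PFKFB3, which makes an activator of phosphofructokinase, fell 2.20-fold and the enolase gene ENO2 1.86-fold. Of 26 measured p53 targets 9 rose and 2 fell, by either adjustment (camera adjusted p = 0.303). TP53I3 rose 2.67-fold, the death receptor gene TNFRSF10B 1.52-fold by its brightest probe, with -0.17 and no call from another and 0.87 from the one left, and the nuclease gene AEN 1.49-fold. The death receptor gene FAS fell 1.37-fold, a call lost under median scaling (limma adjusted p = 0.115).

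B-cell identity genes rose in 10 of 31 and fell in 5 (12 and 5 adjusted over the list alone; camera adjusted p = 0.309). The transcription factor gene POU2F2 was at least 1.92-fold higher, undetected on the shControl arrays (log2 difference 0.73 without background correction), and TNFRSF13C, the receptor for the survival factor BAFF, rose 1.95-fold. Plasma cell markers fell in 7 of 16 and rose in 2, by either adjustment (camera adjusted p = 0.0599). The list passed downward with camera in 7 other settings (adjusted p 0.0145 to 0.0494), but not with an estimated correlation (adjusted p = 0.23). Besides CD38, the secretory chaperone gene MZB1 fell 2.12-fold and the surface receptor gene SLAMF7 1.84-fold, and the disulfide isomerase gene TXNDC5 rose 1.86-fold.

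Markers of other cell types were mostly undetected. Of the T and NK cell markers 6 of 21 were measured, with 3 lower and 1 higher by either adjustment (camera adjusted p = 0.0599). The list passed downward with camera in 6 other settings (adjusted p 0.0335 to 0.0464), but not with an estimated correlation (adjusted p = 0.357). Without the detection filter its median log2 difference went from -0.34 to -0.03 (camera adjusted p = 0.232). NKG7, a cytotoxic granule protein gene, fell 4.13-fold, the interleukin 7 receptor gene IL7R 1.78-fold and CD7 1.45-fold. ZAP70, a T-cell receptor kinase gene detected on 1 of the 3 shControl arrays, was at least 1.26-fold higher (limma adjusted p = 0.0354), a call that most other settings lost (limma adjusted p up to 0.104). Of the myeloid markers 7 of 19 were measured, with 4 lower and 2 higher by either adjustment (camera adjusted p = 0.253; median log2 -0.49, or -0.06 without the filter). The lysosomal protein gene CD68 fell 3.36-fold by its brightest probe, with 0.13 and no call from another and -0.81 as the mean of both, TYROBP fell at least 1.45-fold with detection on 1 of the 3 shTERT arrays, AIF1 1.41-fold with no call from a second probe, and CEBPA rose 1.71-fold. Of the stromal and epithelial markers 6 of 22 were measured, with 2 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.303; median log2 0.30, or 0.01 without the filter). The growth factor receptor gene PDGFRB rose 4.47-fold and the smooth muscle actin gene ACTA2 2.68-fold, and the cadherin gene CDH1 fell at least 2.03-fold with detection on 1 of the 3 shTERT arrays.

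In all, 10 of the 25 lists passed the camera threshold, 4 upward and 6 downward, while 0 passed with an estimated correlation and 22 passed with fry, which asks only whether a list's own genes move on balance one way. With 1 array left out the count fell to 6 without shControl 3, shTERT 1 or shTERT 2, each time through the oxidative phosphorylation, ATF4, MHC class II and immediate early lists, and each of the other arrays left out ended the call of at least 1 list, among them NF-kB targets without shControl 1 (adjusted p = 0.0533). The interferon, mitosis, replication, MYC-induced and Wnt lists passed whichever array was left out, but under the stricter detection filter the Wnt, ATF4 and MHC class II (adjusted p = 0.0877 each), NF-kB (adjusted p = 0.0732) and oxidative phosphorylation lists (adjusted p = 0.103) missed it. The MHC class II list also missed it with cyclic loess (adjusted p = 0.0511), and the MHC class II (adjusted p = 0.256), ATF4 (adjusted p = 0.165) and oxidative phosphorylation lists (adjusted p = 0.293) with median scaling. With the replicate number as a block, the oxidative phosphorylation, NF-kB, ATF4, MHC class II and immediate early lists missed it (camera adjusted p = 0.0524 each).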

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

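The test of neighbouring genes measured from the median of all genes was run first by mistake, and was not the version written down beforehand. Its prediction was written afterwards. The other tests in this part were written down before they were run. The bounds for the interferon and mitosis medians were set after the medians of the main setting were seen.

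Probes that the platform annotation gives no single gene were left out of the counts of genes, yet 1204 of 3900 such probes changed (limma, 699 higher and 505 lower in shTERT). The largest change among them was in ILMN_1673553, which differed by -4.85 on the log2 scale, 28.9-fold lower in shTERT (10.64 ± 0.11 against 5.79 ± 0.10, SD, n = 3, limma adjusted p = 2.73e-06).

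The 10 possible splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. Of these 10 splits, 1, the real one, gave 4584 changed genes, and the highest of the others gave 0 by limma, with 102 to 158 genes at an unadjusted p under 0.05 against 5465 in the real split. The same 1 split gave 2325 genes changed at least 1.5-fold against 0 at most in the others, and 1 split gave 10 gene lists past the threshold against 3 at most. Every other split mixes arrays of both groups on each side. The difference between the groups then adds to the spread within a side, so low gene counts were bound to follow. The other splits therefore do not measure what chance gives.

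Interferon-stimulated genes were lower in shTERT. Normalization between arrays is argued against, since the list's median stayed at -1.28 under median scaling and -1.33 under cyclic loess. It was -1.13 without background correction and -1.17 with the authors' values, but both keep 1 shared distribution between arrays and so do not test this. Myeloid or T cells among the shControl cells stay open: of 12 abundant transcripts of these cells, 5 (S100A8, TYROBP, CD2, IL7R and NKG7) were detected on all 3 shControl arrays, which met neither bound. CD14 was detected on 1 array of each group, and LYZ, S100A9, FCN1, CD3D, CD3E and CD3G on 0 arrays of either group. CD2, IL7R and NKG7 were also detected on all 3 shTERT arrays, S100A8 on 2 and TYROBP on 1. From shControl to shTERT the log2 mean fell from 10.75 to 8.70 for NKG7, 8.763 to 7.934 for IL7R and 5.654 to 4.955 for TYROBP. It differed little for CD2 (6.21 and 6.09) and S100A8 (5.254 and 5.148). An effect of the TERT hairpin and a response of the control culture to its own construct or handling cannot be told apart, because each group holds 1 construct.

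Mitosis and replication genes were higher in shTERT, and the tests below used the mitosis list. Normalization between arrays is argued against, with a median of 1.13 under median scaling and 1.07 under cyclic loess. The median was 0.78 without background correction and 0.81 with the authors' values, settings that again do not test this. A trend with probe brightness is argued against too, as the list's median lay at percentile 100 among 10000 random lists matched on brightness, whose highest median was 0.41. An effect of the hairpin and a different growth state of the cultures at harvest cannot be told apart, since 0 labels give a density, day or harvest.

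The change between the groups was broad. Probe-specific hybridization differences are argued against: across 1228 called genes, which are not independent replicates, the log2 differences of the brightest and the next probe correlated at 0.842 (95% bootstrap interval 0.821 to 0.861), with the same direction in 90.0%. Gain or loss of long chromosome segments in one of the cultures stays open, because the farthest window of 60 neighbouring genes had a permutation p of 0.0989 measured from 0, as written down beforehand, and 0.00899 measured from the median of all genes (0.03), the version that was run first. The farthest windows ran from RANGAP1 to LMF2 (median 0.29) and from ZCCHC7 to SPATA31C1 (median -0.29), and neighbours that share a regulator may give such a p without any change in copy number.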

How the results depend on the processing

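All alternatives here were planned. The count of changed genes lay between 3264 (median scaling) and 5058 (intensity trend and robust estimation) against 4584, with 49.4% to 58.8% of calls higher in shTERT (53.9% in the main setting). Genes changed at least 1.5-fold were 2325 in the main setting, 1335 without background correction and 1339 with normexp and offset 50, settings that add more background to each value by construction. MYC stayed higher and past the threshold in every setting run for it, at 0.37 (mean of its probes) to 0.60, and its second probe passed only with the intensity trend (limma adjusted p = 0.0476). TERT stayed below background. Of 10 gene lists past the threshold, 0 passed with an estimated correlation, and 22 of 25 passed with fry, which asks another question. Estimated correlations lay below the preset 0.01 for the MYC-induced (-0.0201), oxidative phosphorylation (-0.0197), NF-kB (-0.00838), ATF4 (-0.000759) and MHC class II lists (0.000224). A higher correlation among members therefore does not account for the loss of those calls. They lay above it for the replication (0.119), mitosis (0.165), interferon (0.174), Wnt (0.265) and immediate early lists (0.092). With an estimated correlation, camera also takes its p-value at the few residual degrees of freedom of 6 arrays, unlike with the preset one. The unadjusted camera p of the MYC-induced list rose from 0.00112 to 0.017 despite its lower correlation. How far the correlation and the degrees of freedom each bore on the other calls was not tested. Median scaling ended the calls of the ATF4 (adjusted p = 0.165), MHC class II (0.256) and oxidative phosphorylation lists (0.293), cyclic loess that of MHC class II (0.0511), and the stricter filter those of the Wnt, ATF4 and MHC class II (0.0877 each), NF-kB (0.0732) and oxidative phosphorylation lists (0.103). With camera the ribosomal protein list passed in 9 other settings, plasma cell markers in 7, T and NK cell markers in 6 and nucleotide synthesis in 1, all short of the threshold in the main setting. Leaving out 1 array gave 3623 to 4458 changed genes, 2260 to 2422 changed at least 1.5-fold, 6 to 10 lists, MYC differences of 0.46 to 0.60 (limma adjusted p 0.0132 to 0.0292) and TERT differences of -0.07 to 0.03. With the replicate number as a block (replicate block), 4409 genes changed, MYC had a limma adjusted p of 0.0121 and 5 lists passed, as the oxidative phosphorylation, NF-kB, ATF4, MHC class II and immediate early lists missed the threshold (adjusted p = 0.0524 each) and the ribosomal protein list stayed short of it (adjusted p = 0.0745); the block leaves fewer residual degrees of freedom. The replicate numbers did not pair the arrays, as the deviations of same-numbered arrays from their group means correlated at 0.09, 0.03 and 0.04 across probes, although each shTERT array correlated best with the shControl array of its own number, a hint from the data and not from the design. Apart from TERT and MYC, the rule picked genes for a large fold or a small p-value on these same arrays. Such genes were likely to keep direction and call. Among all tested genes, 3132 of the 4584 main calls recurred under median scaling. Over the other results, genes named by the rule kept direction and call in 1984 of 2001 comparisons with an alternative, lost the call in 14 and gained it in 3. Gene lists did so in 396, 42 and 35 of 473, with no called direction reversed. The 18 genes named after their values were seen did so in 294, 5 and 1 of 300 comparisons. The 4 added lists that were tested did so in 71, 1 and 3 of 76. The Notch list, uncalled in both, turned to a median of -0.16 under the stricter filter (0.30 in the main setting). That filter asks for detection on all 6 arrays. HEY2 and LFNG, which rose and were detected on 1 and 2 of the 3 shControl arrays, therefore left the list. The fold of all these genes moved by over 1.5 times in 23 genes without background correction and in 23 with offset 50, in 11 with the authors' values in 3 with the mean of a gene's probes and in 1 without the filter. A block for the chip was not run, since no chip is named. Signal over background limits the dim genes, TERT among them, for which no fold can be given.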

Other observations

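The lists in this part were chosen after the largest changes were seen, except the MHC class I test, which was written down before its genes were looked at but prompted by the interferon-stimulated genes. HEY1, ETV5, MAGEA2, CCL3L1, CCL4L1 and CXCL9, whose changes prompted the lists, were left out of the tests, but other members also stand in the fixed lists: 4 of the 10 tested chemokines (CCL3, CXCL8 and CCL22 among them), 7 of the 11 tested ERK targets (CCND1 among them), 1 of the 19 MHC class I genes and 0 of the Notch and cancer-testis members. The chemokine and ERK tests are therefore not independent of the fixed lists.

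Chemokine genes moved apart. CCL3 and CCL3L1, close paralogs that attract monocytes and T cells, rose 4.02-fold and 4.37-fold in shTERT, and CXCL16, undetected on the shControl arrays, rose at least 1.17-fold (log2 0.01 and no call without the detection filter), while CXCL9, an interferon gamma-induced chemokine, fell 4.67-fold, CXCL8 3.95-fold, CCL22 3.78-fold, CCL20 2.71-fold and CCL17, detected on 1 of the 3 shTERT arrays, 2.49-fold (log2 -0.70 without background correction). Of 10 measured chemokines other than CCL3L1, CCL4L1 and CXCL9, 3 rose and 6 fell. Whether chemokines rise together was not decided, since the list did not pass (camera over the added lists, adjusted p = 0.267, downward).

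Among Notch targets, HEY2, detected on 1 of the 3 shControl arrays, rose at least 2.37-fold (log2 0.75 without background correction), LFNG, a glycosyltransferase that modifies Notch detected on 2 of them, 3.32-fold (likewise 1.00) and HEYL 1.81-fold, while HES4 fell 1.58-fold. Without HEY1, 4 of 10 measured members rose and 2 fell. Whether the targets rise together stays open (camera adjusted p = 0.362). Under the stricter filter, which HEY2 and LFNG do not pass, the direction turned downward (camera adjusted p = 0.599). Among ERK targets, ETV5, a transcription factor, rose 4.08-fold (log2 1.28 without background correction), and 4 of 11 other members rose and 2 fell (camera adjusted p = 0.447). The cancer-testis list had 3 measured members besides MAGEA2, too few for the test, of which PRAME fell by 0.59 on the log2 scale, with no call from a second probe, and none rose.

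MHC class I antigen presentation was tested as a companion of the interferon-stimulated genes. Of 19 measured members 11 fell and 0 rose, with a median log2 difference of -0.43 (camera adjusted p = 0.000396; adjusted p = 0.0535 with an estimated correlation). HLA-E fell 1.97-fold, the peptide transporter gene TAP1 1.94-fold, HLA-C 1.77-fold and HLA-B 1.59-fold, though the probes of HLA genes may read several of them, and B2M, the shared light chain, gave -0.18 (limma adjusted p = 0.189; 0.0422 with the intensity trend). The fall is consistent with a lower interferon response in shTERT cells or a higher one in shControl cells, which 1 construct per group cannot separate.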
